A study of Mus musculus with 15 samples.

How the data were processed

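Gene expression in mouse kidney was measured on 15 Affymetrix mouse gene arrays. Per the labels, 4 arrays hold single cells of the metanephric mesenchyme (MM), the embryonic tissue that gives rise to the nephrons, picked at embryonic day 11.5 from mice carrying a Crym-GFP transgene. Another 5 arrays hold single fluorescent cells of the juxtaglomerular (JG) complex of adult male mice with a renin-driven YFP reporter. Adult cortex was sampled as a lysate of many cell types and labelled in 2 ways, with 3 libraries each. The diluted cortex was amplified with the single cell protocol, for which the labels record 32 rounds, and the standard-labelled cortex with a NuGEN kit, for which they record 1 round. Cells carry the numbers of their labels, 14, 15, 16 and 19 for MM and 4 to 8 for JG, and cortex libraries carry the letters A, B and C.

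The deposited values are log2 probe set signals, between 2.22 and 13.98 over 35557 probe sets with no missing value. Affymetrix Expression Console is the tool named in the submitters' processing notes. Its version, the summary algorithm and any normalization between arrays are not given in the sources used here, so the values were used as deposited, on the log2 scale, as the values show it. Array medians differed between groups, and the report sets differences beside the shift of a background class. An array has no count depth, and its number of probe sets and of arrays limits the precision.

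Probe sets were named from the platform annotation supplied with the values, which lists 23410 of them. Of these, 21789 carry 1 gene symbol and 1621 carry several, while 12147 probe sets are unlisted and stayed unnamed. Through the RefSeq gene table of assembly GRCm38.p6, 21698 probe sets matched and 0 changed symbol. The annotation names no genome build, so no coordinates are printed. In all, 19938 genes had a probe set of their own. A gene with several probe sets was represented by the brightest over the 15 arrays, and among the genes farthest apart by the probe set with the largest difference.

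Comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For the cells, no label names an animal, so each group of cells counts as 1 sample. Their comparisons have no test, no p and no count of changed genes. They are given as differences of group means on the log2 scale, with SDs over cells. Each list of genes is given by the median difference of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean expression. Mean expression was taken over both groups compared. A list that differs between the groups is thus matched to genes dimmer in its higher group. Such genes can differ less, so the percentile can be too extreme. Some lists were also matched on the level in diluted cortex, the others were not. Named genes of the cell comparisons were the 10 with the highest and the 10 with the lowest difference. They had to reach the median of all probe sets in the higher group, and every sample of one group had to lie beyond every sample of the other. Up to 4 members per list with the largest difference, Crym, Six2, Xist and Y-linked genes could be named too. Genes described cell by cell were chosen after their values were seen.

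The cortex libraries labelled in 2 ways were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05. A probe set entered if its mean in the higher group reached the median of all probe sets. The 10 highest and 10 lowest log2 fold changes past the threshold were named. Lists were tested with camera at its preset correlation of 0.01, and again with the correlation estimated per list, with adjustment over 29 lists. Nothing says that the cortex libraries come from separate animals, so p-values measure only the spread between these samples, which may be technical. Other values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

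The lists cover renin cells, contractile smooth muscle, pericytes and mesangium, the cAMP and PKA pathway, the Notch pathway, and lysosomes and granules. Others mark proximal tubule, thick ascending limb, distal convoluted tubule, collecting duct principal cells, intercalated cells, podocytes, endothelium, macrophages and leukocytes, interstitial fibroblasts and erythroid cells. For the embryo there are lists for cap mesenchyme, kidney stroma progenitors, ureteric bud, nascent nephron, cell cycle, and fetal growth and imprinted genes. Further lists hold immediate early and heat shock genes, nuclear-encoded respiratory chain genes, Y-linked genes, Xist, ribosomal proteins, replication-dependent histones, small nucleolar RNAs, mitochondrially encoded genes, and olfactory and vomeronasal receptors. Of the 31 lists, the list of mitochondrially encoded genes had 0 measured members. Over all lists 32 fixed members, the renin gene among them, are not analysed here.

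Receptors of the nose served as a background class, with 1205 probe sets of 1190 genes. Their median difference is the background shift of a comparison. The 99th percentile of their values on an array was taken as the level above which a gene stood out from background, a choice made after the data were seen. The limma step was tested on simulated data for the 2 cortex groups with 18202 probe sets, 200 of them changed. It called 80.0% of changes of log2 size 1 and 23.0% of changes of size 0.5, and 4 of its 107 calls were of unchanged probe sets. On simulated lists of 15 genes drawn from 19938, 1 of 50 unshifted lists and 48 of 50 lists shifted by 2 lay outside the central range of random lists. The simulated differences were independent between genes and unrelated to mean expression. Correlation within lists and the matching on expression were therefore not tested.

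Alternatives were quantile normalization (R, limma), centring each array on its median, other filters on dim probe sets, and a trended robust variance model. Group medians, means of linear values, the mean of all probe sets of a gene, leaving out each sample in turn, the library letter as a block, and the standard-labelled cortex as comparator were tried as well. Centring on the receptors, leaving out JG cells 4 and 5 together, and all alternatives for MM cells against diluted cortex were added after the data were seen.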

Results

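Expression was measured on 15 arrays in 4 groups: 4 single cells of the metanephric mesenchyme (MM) at embryonic day 11.5, 5 single juxtaglomerular (JG) cells of adult kidneys, 3 libraries of diluted adult cortex amplified with the single cell protocol, and 3 libraries of standard-labelled adult cortex. Array medians were close to each other, at 6.03 to 6.21 in MM cells, 6.20 to 6.28 in JG cells, 5.73 to 5.74 in diluted cortex and 5.89 to 5.96 in standard-labelled cortex (log2). The background differed more. Olfactory and vomeronasal receptors, which kidney cells are not known to need in number, had medians of 4.86 to 5.26 in MM cells and 5.04 to 5.35 in JG cells, against 4.15 to 4.17 in diluted and 4.19 to 4.22 in standard-labelled cortex. The share of named probe sets above the 99th percentile of these receptors on the same array was 12.2% to 23.0% in MM cells and 7.51% to 15.4% in JG cells. It was 50.6% to 52.9% in diluted cortex and 46.8% to 51.4% in standard-labelled cortex. JG cell 5 (7.51%) and JG cell 4 (9.90%) had the lowest shares. Among MM cells, cell 16 had the lowest (12.2%).

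Cells differed from each other far more than cortex libraries did. Across probe sets, which are not independent replicates, Pearson correlations within a group were 0.748 to 0.835 for MM cells and 0.754 to 0.839 for JG cells, 0.991 to 0.995 for diluted cortex and 0.989 to 0.992 for standard-labelled cortex. The median SD of a probe set was 0.375 over the 4 MM cells and 0.375 over the 5 JG cells, against 0.113 and 0.138 over the 3 diluted and the 3 standard-labelled libraries. No 2 arrays correlated above 0.995, and none held the values of another.

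Genes that check the labels gave a mixed picture. Crym, a thyroid hormone binding protein whose regulatory sequence drives the GFP of the MM line, measured 8.61 in MM cell 16 and 6.90 to 7.50 in the other MM cells, near the background level of those arrays. It was far higher in adult cortex, at 11.02 to 11.20 in the diluted and 8.16 to 8.28 in the standard-labelled libraries. Six2, a transcription factor of nephron progenitors, reached 10.13 in MM cell 16. Xist, the RNA of the inactive X chromosome, lay below the background level in all 15 arrays, with its highest value, 6.78, in MM cell 15. Of the Y-linked genes, Eif2s3y, a translation factor, measured 8.17 to 8.71 in diluted and 8.81 to 8.99 in standard-labelled cortex but 4.31 to 5.59 in the JG cells, all labelled male. It reached 8.18 in MM cell 14, whose sex the labels leave open. The demethylase genes Uty (8.06 to 8.39) and Kdm5d (7.42 to 7.67) stood above background in standard-labelled cortex, while diluted cortex gave 5.35 to 5.55 and 5.13 to 5.47. Usp9y, which encodes a deubiquitinase, measured 3.58 to 5.26 and stayed below background on every array.

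JG cells were set against cortex that was diluted and amplified in the same way, the comparison for which the labels say the diluted cortex was made. JG cells carried high levels of Mgp, which encodes an inhibitor of calcification, and of Crip1, which encodes a LIM domain protein. Mgp measured 13.36 ± 0.12 (SD over 5 cells) against 10.17 ± 0.39 in diluted cortex (SD, n = 3), a difference of 3.19, and Crip1 12.40 ± 0.44 against 8.87 ± 0.26, a difference of 3.53. The phosphatase gene Ptp4a3 (11.45 ± 1.13), the sodium pump regulator Fxyd1 (10.88 ± 2.26) and the predicted gene Gm13889 (10.45 ± 2.12) were higher by 3.42, 3.44 and 3.55. MM cells, amplified alike, held these 5 genes at 6.86 to 8.02 on average, where the receptor 99th percentile of their arrays was 7.13 to 7.56. The MM means of Mgp (6.86) and Crip1 (7.20) lay below or within that span. Those of Gm13889 (7.75), Fxyd1 (7.96) and Ptp4a3 (8.02) lay above it. Not every JG cell was high in all of them. Fxyd1 measured only 8.37 and 8.50 in JG cells 4 and 5, and Gm13889 only 8.70 and 8.25 in JG cells 5 and 6. The means of Fxyd1 and Gm13889 thus join high and low cells. Receptors themselves were 1.02 higher in JG cells than in diluted cortex, with a 99th percentile of 1.79 and a maximum of 1.95, so that part of each difference was shared by background.

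The other genes of the rule were higher in MM cells as well. The ribosomal RNA gene n-R5s136 was 3.07 higher in JG cells than in diluted cortex, the predicted gene Gm13213 2.91, the linker histone H1f10 2.77 and the focal adhesion gene Tns1 3.03, while the MM means of these genes also exceeded diluted cortex by 1.71 or more. The splicing factor Tra2a was 2.99 higher in JG cells and 1.45 higher in MM cells. Single cells raised 2 of these JG means. H1f10 measured 12.66 in JG cell 5 and 8.27 to 9.48 in the other JG cells, and its MM mean was 9.71. Tra2a measured 13.25 in JG cell 4 and 9.31 to 9.84 in the other JG cells. Tns1 has 6 and Tra2a 3 probe sets, of which the largest difference is given, and the lowest differed by -1.03 and -2.15.

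The genes lowest in JG cells relative to diluted cortex included Slc27a2 and Fbp1 of the proximal tubule list. Slc27a2, an acyl-CoA synthetase and fatty acid transporter, measured 5.82 ± 0.49 over the 5 cells against 13.19 ± 0.06 in diluted cortex, a difference of -7.36. The gluconeogenic enzyme Fbp1 differed by -6.68, the amino acid transport protein collectrin (Cltrn) by -7.15, the glucuronosyltransferase Ugt2b38 by -6.78 and the protease inhibitor Spink1 by -6.92. H2bc4, a core histone gene, differed by -7.91, the deaminase gene Rida by -7.69 and the scramblase gene Plscr2 by -6.63. The mitochondrial chaperonin Hspe1 (-6.97) and the respiratory complex I subunit Ndufc2 (-6.65) belong to most cell types. MM cells held Hspe1 at 11.67 and Ndufc2 at 12.45, close to the 11.73 and 12.64 of diluted cortex, so that low values of these genes were seen in JG cells and not in MM cells. The JG means of all 10 genes lay below the receptor 99th percentile of every JG array (7.55 to 7.93), so these differences are set against background signal and are bounds, whose order says little.

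**Figure D1:**
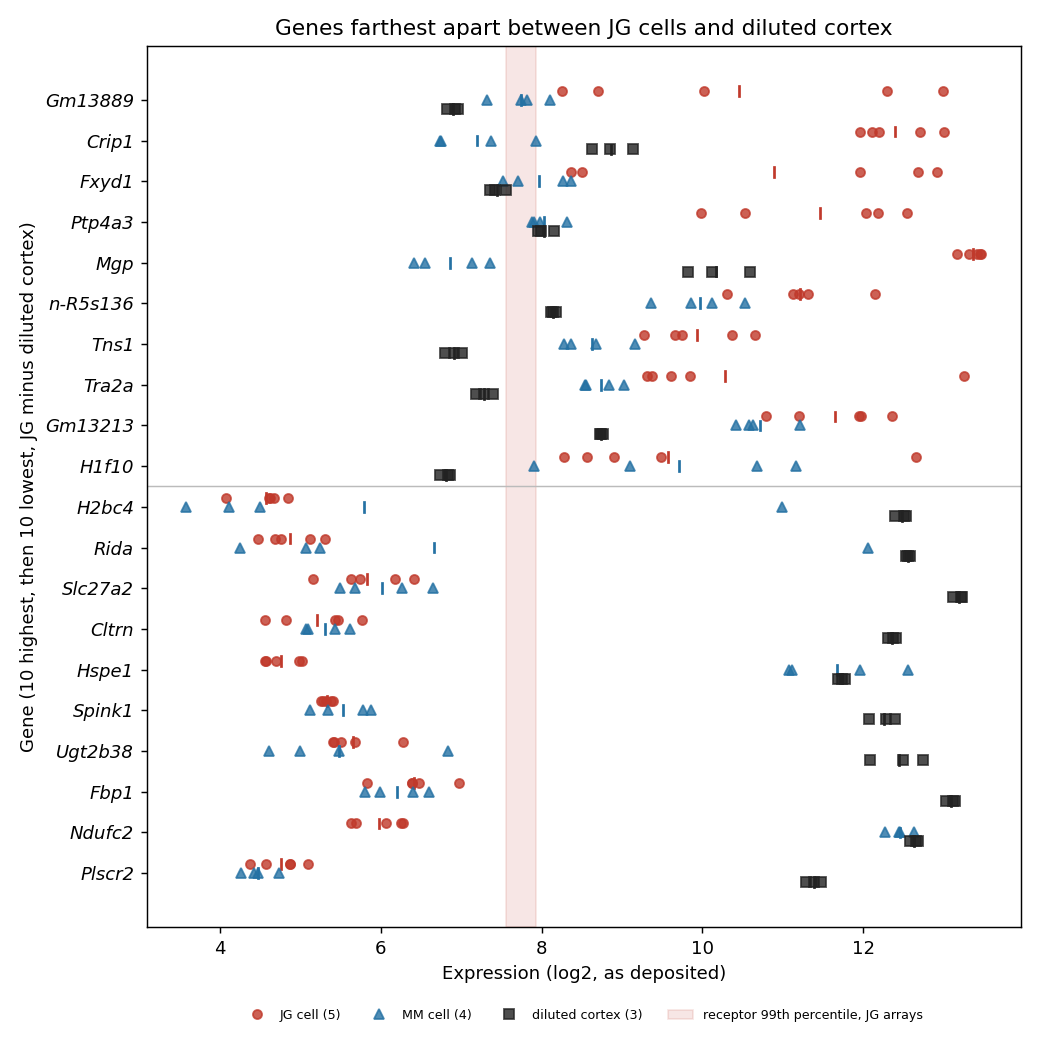
Expression (log2, as deposited) of the 10 genes highest and the 10 genes lowest in JG cells relative to diluted cortex, with 1 point per JG cell, MM cell or diluted cortex library, a vertical tick at each group mean, and the shaded band spanning the receptor 99th percentile of the JG arrays. All JG cells hold Mgp above 13, while Hspe1 and Ndufc2 are low in JG cells and not in MM cells.

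Genes of the proximal tubule and of the thick ascending limb were low in JG cells. All 25 measured proximal tubule genes lay at least 1 log2 unit below the background shift, with a median difference of -4.85, lower than in all 10000 random lists of the same mean expression (percentile 0). Gatm, an enzyme of creatine synthesis, differed by -6.56. The 11 thick ascending limb genes had a median of -3.90 (percentile 0.01), with uromodulin (Umod) at -5.70 and the salt transporter Slc12a1 at -4.46. The 8 distal convoluted tubule genes had a median of -2.65 (percentile 1.21), among them the calcium buffer Calb1 at -5.11. Among random lists matched on the level in diluted cortex instead, proximal tubule lay at percentile 0.04 and thick ascending limb at 1.54. The distal convoluted tubule list was not matched in that way. Medians were -2.22 for 10 collecting duct principal cell genes (percentile 8.16), with Hsd11b2 at -3.79, and -0.93 for 11 intercalated cell genes (percentile 24.5). The collecting duct and intercalated cell medians lay inside the central range of random lists, and against standard-labelled cortex the collecting duct median was 0.05.

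Other compartments of the cortex stood less apart. The 16 endothelial genes had a median of -0.97 (percentile 17.0), with the sialomucin Emcn at -3.84, and the 16 macrophage and leukocyte genes a median of -0.73 (percentile 4.11), with the antigen presentation chaperone Cd74 at -2.91. Against standard-labelled cortex these medians were 0.14 and 0.42, of opposite sign. The 10 podocyte genes had a median of 0.43 (percentile 57.6), the 7 erythroid genes 0.17 (percentile 32.4) and the 14 interstitial fibroblast genes 0.70 (percentile 91.6). Relative to the receptors all 3 were negative, at -0.60, -0.86 and -0.32.

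Lists for renin cells and muscle did not stand apart as wholes. The 14 measured renin cell genes had a median difference of 0.69 (percentile 70.6), which is -0.33 relative to the receptors, so that its sign depends on the reference. Apart from Crip1, the G protein regulator Rgs2 differed by -1.93 and the adenylyl cyclase Adcy6 by 1.01. Contractile smooth muscle genes (17) had a median of 0.36 (percentile 83.3) and pericyte and mesangial genes (16) one of 0.83 (percentile 89.8), or -0.66 and -0.20 relative to the receptors. The median over 18 genes of the cAMP and PKA pathway, which drives renin transcription, was 0.62 (percentile 40.8), below the background shift and -0.75 against standard-labelled cortex, and the PKA regulatory subunit Prkar1a differed by -3.95. The 16 Notch pathway genes had a median of 1.28 (percentile 99.9), 0.25 beyond the shift, with the coactivator Maml2 at 1.89, the target gene Heyl at 1.76 and the ligand Dll4 at 1.47. No Notch gene lay 1 log2 unit or more above the shift.

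Among lists of general cell functions, lysosomal and respiratory genes were the lowest. The 17 lysosome and granule genes had a median of -4.08 (percentile 0.02), with the protease Lgmn at -6.40 and the membrane protein Lamp2 at -6.15, and all 17 lay at least 1 log2 unit below the shift. The 19 nuclear-encoded respiratory chain genes had a median of -3.94 (percentile 0.06), with Uqcrc2 at -5.94 and Ndufb8 at -5.52. Among random lists matched on the level in diluted cortex instead, the lysosome and respiratory chain medians lay at percentiles 17.3 and 52.8, inside the central range. Ribosomal protein genes (61) had a median of -0.90, higher than all random lists of like expression, whose medians centred on -2.17. Its sign rests on JG cells 4 and 5, since it was 0.17 without them and 0.11 with group medians. In JG cells 6, 7 and 8 the ribosomal protein median was 12.3 to 12.4, against 8.50 and 8.57 in JG cells 4 and 5. Small nucleolar RNAs (51) had a median of 0.68 (percentile 0.230), replication-dependent histones (22) one of 0.80 (percentile 88.2), the 4 Y-linked genes 0.18 (percentile 3.72, and -3.31 with dim members left out), immediate early and heat shock genes (19) 0.34 (percentile 96.0), all of them below the background shift and so negative relative to the receptors. With dim members left out, Eif2s3y alone stayed on the Y-linked list. Xist differed by 1.03, which equals the shift. Each embryonic list except that for fetal growth lay below the shift: cap mesenchyme (23 genes) 0.77, stroma progenitors (15) 0.26, ureteric bud (17) 0.08, nascent nephron (13) 0.55 and cell cycle (27) 0.08. Fetal growth and imprinted genes (14) had a median of 1.21 (percentile 98.5), 0.18 beyond the shift.

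Some JG cells carried contractile and pericyte genes at high level. Acta2, the smooth muscle actin, reached 12.20 in cell 7 and 11.32 in cell 8, each against a median of 6.75 over the other 4 cells. The myosin light chain Myl9 reached 12.79 in cell 7, the calcium pump regulator Pln 12.32 and the intermediate filament desmin (Des) 10.60 in cell 8. Gja4, a gap junction protein of vessels, reached 12.23 in cell 7. The pericyte gene Rgs5 measured 10.44 in cell 4 and 10.55 in cell 7, and Ndufa4l2 11.49 in cell 5 and 11.41 in cell 6, with medians over the 5 cells of 9.76 and 10.92, so that high values of Rgs5 and Ndufa4l2 were not confined to these cells. The granule membrane protein Cd63 reached 12.43, 12.13 and 11.69 in cells 4, 6 and 7, and the lysosomal protease Ctsl 12.38 in cell 4 and 10.76 in cell 6.

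Stress genes and markers of other cell types appeared in single JG cells too. The immediate early genes Junb (12.29) and Zfp36 (9.89) stood out in cell 4, Zfp36 (10.89) in cell 7 and Ier2 (10.93) in cell 8. The tubule calcium binding protein S100g measured 13.05 in cell 5 and 13.07 in cell 8, near the 12.21 of diluted cortex. Cell 5 also held the proximal tubule genes Gpx3 (12.37) and Miox (12.63) and the endothelial junction gene Cldn5 (10.77). The replication genes Pcna (11.64) and H4c8 (12.73) stood out in cell 6. Of the 25 proximal tubule genes, 1, 3, 2, 1 and 5 were above background in cells 4 to 8, against all 25 in each cortex library.

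MM cells were compared with JG cells, both amplified as single cells, to describe embryonic progenitors beside adult cells. The spliceosomal protein Snrpe measured 12.16 ± 0.18 (SD over 4 cells) against 5.01 ± 0.51 in JG cells (SD over 5 cells), a difference of 7.15. The histone variant H2az2 was higher by 6.48, the S phase entry kinase Cdk4 by 5.51, the nuclear transport regulator Ranbp1 by 5.37 and the splicing factor Srsf9 by 5.31. The antioxidant enzyme Prdx2 was higher by 6.99, Hspe1 by 6.91, Ndufc2 by 6.47, the prolyl isomerase Fkbp3 by 6.06 and the zinc finger gene Zfp706 by 5.59. Zfp706 and Prdx2 have 2 probe sets each, the other one differing by 0.99 and 4.23. The JG means of these 10 genes lay below the receptor 99th percentile of every JG array, so the differences are bounds, and Prdx2 reached 11.17 in JG cell 6. Receptors differed by -0.21 between the groups, so the background shift was small here.

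Among genes lower in MM cells, Mgp differed by -6.50 (6.86 ± 0.45, SD over 4 MM cells), Igfbp7, which encodes a secreted binding protein of insulin-like growth factors, by -5.45 and Crip1 by -5.20. The small heat shock protein Hspb1 differed by -4.52, the actin binding thymosin Tmsb4x by -3.79, the mitochondrial protein Chchd10 by -3.70 and the aldehyde dehydrogenase Aldh7a1 by -3.43. Ptp4a3 (-3.43), Fxyd1 (-2.92) and Ndufa4l2 (-2.92) completed the list. The MM means of Mgp, Igfbp7, Crip1, Aldh7a1 and Ndufa4l2 (6.83 to 7.28) lay within or below the span of the receptor 99th percentile on MM arrays (7.13 to 7.56), so their differences are bounds. Aldh7a1, Igfbp7 and Chchd10 measured 10.69, 12.94 and 11.94 in diluted cortex, close to or above the JG means of 10.71, 12.38 and 11.61.

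Cell cycle genes were higher in MM than in JG cells as a group. The 27 genes had a median difference of 0.66, 0.88 beyond the background shift and higher than all 10000 random lists. The replication clamp Pcna was higher by 4.39, the kinase subunit Cks2 by 3.38 and the helicase Mcm4 by 2.71. The median was 0.15 without MM cell 14, 0.32 without MM cell 19 and 1.09 without MM cell 16. Fetal growth and imprinted genes (14) had a median of 0.38 (percentile 99.2), with Mest at 4.58 and the cell cycle inhibitor Cdkn1c at 1.99. Their median was 0.11 without MM cell 19 and 0.57 without MM cell 14.

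Respiratory chain genes were higher in MM cells than in most JG cells. The 19 respiratory chain genes had a median difference of 1.64 (percentile 97.4, just inside the central range of random lists, -0.31 to 1.65), and 16 of them lay at least 1 log2 unit above the shift, Ndufb8 by 4.18 and Uqcrfs1 by 3.51 before it was taken off. JG cell 7 had a respiratory chain median of 10.26, above the 9.86 of MM cell 16. Ribosomal protein genes (61) had a median of 1.06, inside the central range of random lists (percentile 92.4), and of -0.03 with group medians. It reflects JG cells 4 and 5 (8.50 and 8.57), since JG cells 6, 7 and 8 (12.32, 12.35 and 12.32) were close to the MM cells (12.35 to 12.56). Lower than most random lists were immediate early and heat shock genes (-0.45, percentile 0.300), with Zfp36 at -1.99 and the chaperone Hspa1a at -1.77, and ureteric bud (-0.41, percentile 0.950) and erythroid genes (-0.48, percentile 1.56). The renin cell list had a median of -0.34 (percentile 5.88), with Gja4 at -1.98 and the angiotensin receptor Agtr1a at -1.81.

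Progenitor lists as wholes differed little between MM and JG cells. Cap mesenchyme genes (23), the markers of nephron progenitors, had a median difference of -0.07 (percentile 90.1), which is 0.14 relative to the receptors and so depends on the reference for its sign, with the limb and kidney patterning gene Hoxd11 at 0.97. Stroma progenitor genes (15) had a median of 0.01 (percentile 95.4), and of -0.06 with group medians, with the transcription factors Meis2 at 1.68, Meis1 at 1.49 and Foxd1 at 1.37. Of the 23 cap mesenchyme genes, 6 to 11 reached the 75th percentile of all probe sets on an MM array, against 7 to 12 on a JG array and 2 to 4 on a diluted cortex array. Measured against the receptor 99th percentile of the array, which was lowest in cortex and lower on MM arrays (7.13 to 7.56) than on JG arrays (7.55 to 7.93), 7, 6, 8 and 5 of them stood above background in MM cells 14, 15, 16 and 19, against 1, 3, 3, 2 and 7 in JG cells 4 to 8 and 10 or 11 in diluted cortex. By group means, 8 stood above background in MM cells and 1 in JG cells.

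Several developmental genes, looked at after their values were seen, stood out in 1 or 2 of the MM cells. Cell 16 held Six2 at 10.13, and its Pcna measured 7.44 against 12.64 to 12.81 in the other MM cells. Its share of named probe sets above background was the lowest of the MM cells, at 12.2% against 17.5% to 23.0%. Low values in cell 16 were not told apart from low signal on its array. Cell 15 held the cap mesenchyme transcription factor Uncx at 11.26, the growth factor Bmp7 at 11.16 and Meis1 at 11.00. Cell 19 held some stroma genes, with Foxd1 at 11.33, Meis2 at 10.97 and the collagen Col3a1 at 10.62. It also held the matrix protein Postn at 9.34, Sox9 at 10.68 and the fetal RNA binding protein Igf2bp1 at 9.95. Of the 15 stroma progenitor genes, 5, 4, 3 and 6 stood above background in MM cells 14, 15, 16 and 19, so the list set cell 19 apart only a little. Cell 14 held the endothelial gene Emcn at 11.77, the matrix gene Fbln1 at 11.18 and Foxd1 at 9.03. The imprinted gene Dlk1 reached 10.52 in cell 15 and 10.46 in cell 19, and Ndn 10.39 in cell 14 and 10.29 in cell 19.

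Some cell cycle genes stood out in cell 14, with survivin (Birc5) at 11.16, the kinase Aurkb at 10.84, the anaphase activator Cdc20 at 10.40 and the replication gene Mcm5 at 11.14. Cell 19 held the mitotic kinase Cdk1 at 11.15 and the nucleotide synthesis enzyme Rrm2 at 11.56. In cell 14 Cdk1 measured 6.49, below the receptor 99th percentile of that array (7.15). Of the 27 cell cycle genes, 16 in cell 14, 12 in cell 19 and 9 in each of cells 15 and 16 reached the 75th percentile of their array. JG cells had 6 to 8 and diluted cortex libraries 6 or 7. Above the receptor 99th percentile were 16, 5, 3 and 12 of them in MM cells 14, 15, 16 and 19, against 1 to 3 in JG cells and 18 in each diluted cortex library. Of all named probe sets, 22.5%, 17.5%, 12.2% and 23.0% stood above it in these MM cells.

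**Figure D2:**
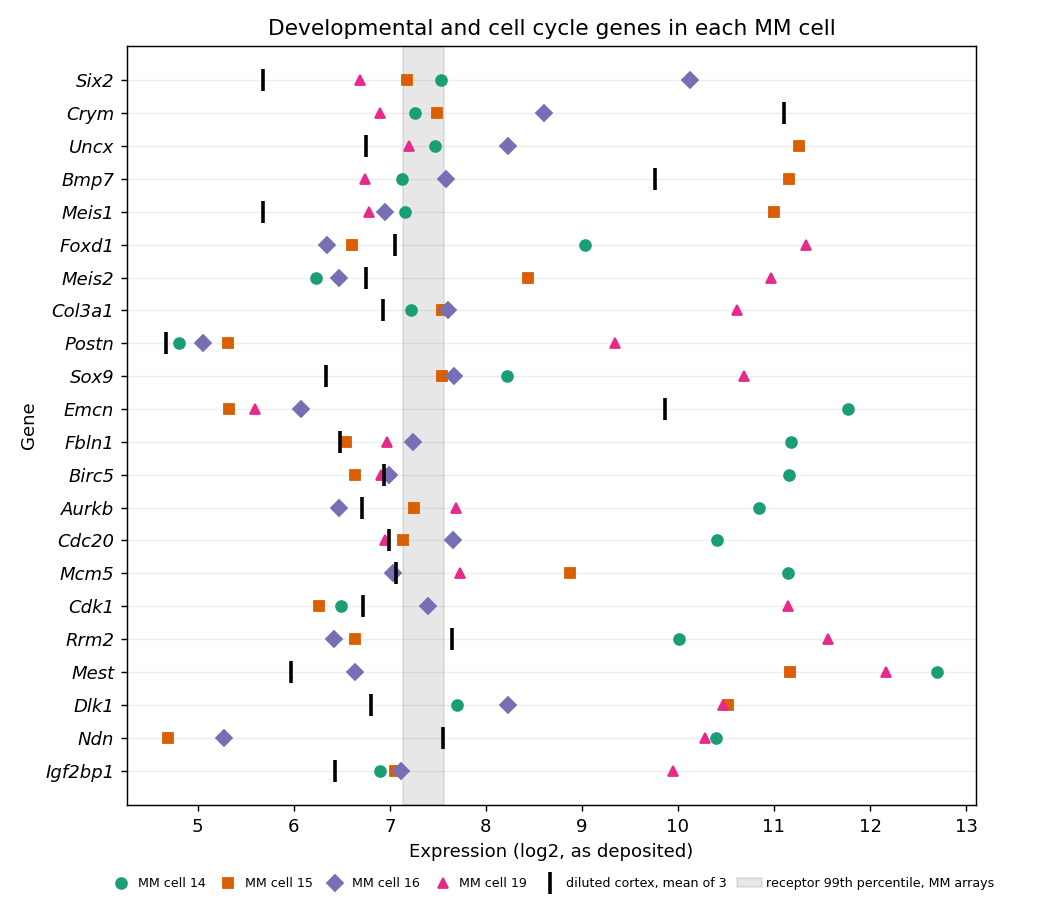
Expression (log2, as deposited) of developmental and cell cycle genes in the 4 MM cells, with 1 symbol per cell, a black tick at the mean of the 3 diluted cortex libraries, and the shaded band spanning the receptor 99th percentile of the MM arrays. Six2 is highest in cell 16 (10.13), Uncx and Meis1 in cell 15, Foxd1 in cell 19 and Birc5 in cell 14.

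Set against diluted cortex, MM cells held little of the nephron transcripts and more of the fetal growth genes. The proximal tubule list (25 genes) had a median difference of -5.22 (percentile 0), with Gatm at -7.26, the thick ascending limb list one of -3.35 (percentile 0.050) and the lysosome list one of -4.28 (percentile 0), with Lamp2 at -6.21. Fetal growth and imprinted genes (14) had a median of 1.58 (percentile 100), 0.77 beyond the receptor shift of 0.81, with Mest at 4.70 and the noncoding RNA Meg3 at 2.97. Cell cycle genes had a median of 0.88 (percentile 99.97), 0.07 beyond the shift, although 13 of the 27 stood above background by the MM mean and 18 by the diluted cortex mean. The cap mesenchyme list had a median of 0.80 (percentile 98.4), which is -0.01 relative to the background shift and takes a negative sign, -0.04, when arrays are centred on the receptors. Respiratory chain genes had a median of -1.75 (percentile 3.38), and ribosomal protein genes 0.27 (percentile 100), which lies below the shift and is -0.10 with arrays centred on their medians.

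The 2 cortex groups come from the same region of adult kidney and differ in dilution, rounds of amplification and labelling kit at once. Nothing in the labels says that they share lysates, so their comparison gives the sum of these differences. Diluted cortex gave more signal than standard-labelled cortex for the mitochondrial enzyme Acads, by 5.20 ± 0.09 (SE) on the log2 scale (limma adjusted p = 2.94e-08, 3 libraries against 3), for the depalmitoylase Abhd17a (5.05), the urate transporter Slc22a12 (4.98), the branched-chain keto acid enzyme Bckdha (4.95) and the membrane protease hepsin (Hpn, 4.93). The mitochondrial quality control kinase Pink1 (4.71), the growth factor binding protein Igfbp4 (4.71), the hydroxylase Dohh (4.65), the water channel Aqp2 (4.50) and the endocytic coreceptor amnionless (Amn, 4.45) followed. Lower in diluted cortex were the noncoding RNAs Rn7sk (-8.21 ± 0.23) and Malat1 (-7.47 ± 0.11), the ubiquitin ligase Rbbp6 (-6.46), the endosomal protein Dnajc13 (-6.44), the RNA helicase Ddx6 (-6.38) and 4932438A13Rik (-6.10). The nucleolar factor Taf1d (-6.09), the membrane protein Lmbrd2 (-6.01), the chromatin remodelling subunit Pbrm1 (-5.58) and the ribonuclease Zc3h12c (-5.45) were next. The 10 lower genes in diluted cortex, and Dohh in standard-labelled cortex, lay below the receptor 99th percentile of every array of their group, so their fold changes are bounds and their order says little. For these 20 genes the limma adjusted p was at most 1.44e-07, and every library of a group lay beyond every library of the other.

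Of 19531 probe sets tested with limma, 7430 were higher and 7169 lower in diluted cortex, 14599 in all. The median over all probe sets differed by -0.09. With a filter at the 75th percentile, 11101 were tested and 4467 were lower. Uty (-2.73) and Kdm5d (-2.25) fell below background in diluted cortex, and Eif2s3y differed by -0.51 (limma adjusted p = 0.0151).

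Of the lists, lysosomal genes had the smallest p at the preset correlation and gave more signal in diluted cortex. With an estimated correlation the collecting duct list had the smallest (limma camera p = 0.0367, against 0.0819 for lysosome). Of 17 tested members 13 were higher and 2 lower, with a median log2 fold change of 1.37, the proteases Ctsz (2.80) and Ctsa (2.09) and the growth factor precursor Grn (2.43) among them (limma camera adjusted p = 0.0184, and adjusted p = 0.516 with an estimated correlation). Of 9 collecting duct principal cell genes 7 were higher and 1 lower, with a median of 2.19, led by the water channels Aqp2 (4.50) and Aqp3 (2.87) and the steroid enzyme Hsd11b2 (3.77) (limma camera adjusted p = 0.0434, and adjusted p = 0.516 with an estimated correlation). Of 15 genes of the cAMP and PKA pathway 11 were lower and 1 higher, with a median of -0.69, and the largest falls were those of the coactivators Ep300 (-4.24) and Crebbp (-3.64) and of the transcription factor Creb1 (-2.25) (limma camera adjusted p = 0.0486, and adjusted p = 0.516 with an estimated correlation). With the filter at the 75th percentile all 3 calls were lost too (limma camera adjusted p = 0.0537 for lysosome and for collecting duct, 0.0927 for cAMP). The collecting duct and cAMP calls were also lost under quantile normalization (limma camera adjusted p = 0.0573 and 0.124), median centring (0.0588 each) and with the library letter as a replicate block (0.0557 each). The cAMP call was lost as well with a trended robust prior (limma camera adjusted p = 0.0597), without diluted library B (0.0609) and without standard-labelled library B (0.0564) or C (0.0583).

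No other list passed limma camera. Cell cycle genes had 13 higher and 1 lower of 21 (median 0.54, limma camera adjusted p = 0.126, and 0.0440 without standard-labelled library B). Macrophage and leukocyte genes had 10 higher and 3 lower of 14 (median 0.98, limma camera adjusted p = 0.145, and 0.00701 with no filter on dim probe sets), Cd74 by 3.40 and the complement gene C1qa by 2.63. Small nucleolar RNAs had 13 lower and 4 higher of 23 (median -0.58), Snord104 by -4.09, and the 3 tested Y-linked genes were lower (median -2.25), both at limma camera adjusted p = 0.145. Proximal tubule genes went both ways, 14 higher and 9 lower of 25, from 4.98 for Slc22a12 to -3.53 for the endocytic receptor Cubn and -3.11 for Lrp2. Renin cell genes had 3 higher and 5 lower of 11, with Gja4 up by 1.77 and Pde3b at -1.46. Their median (0.12) and mean (-0.04) differed in sign, as did those of contractile smooth muscle (-0.24 and 0.18), the Notch pathway (0.08 and -0.09), pericytes (0.03 and -0.02), intercalated cells (0.43 and -0.02) and fetal growth genes (0.09 and -0.08). For nascent nephron genes the median was 0.07 and the test pointed down. Counts adjusted over the list alone were the same for the lists named here except fetal growth genes, where 2 were higher in place of 3.

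**Figure D3:**
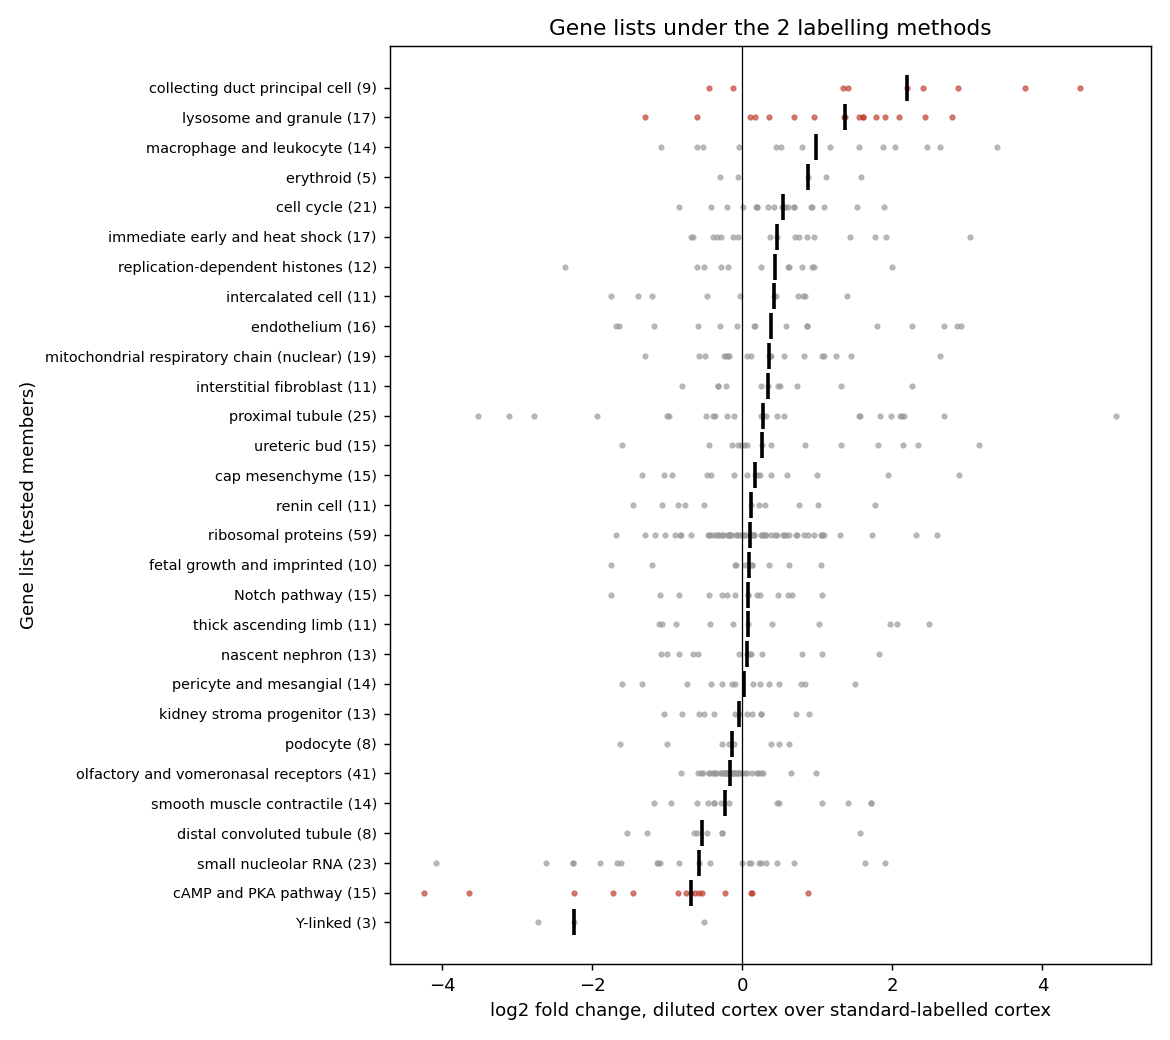
Log2 fold change of diluted over standard-labelled cortex for the tested members of each gene list (1 point per gene, list size in brackets), with a black bar at each list median and red points for the lists past a camera adjusted p of 0.05 at the preset correlation. The collecting duct (median 2.19) and lysosome (1.37) lists lie highest among the red lists and the cAMP and PKA pathway list (-0.69) lowest.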

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

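All tests in this part were chosen only after the result was seen, except the removal of the trend in gene span from the 20 named genes.

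In 40 of 264 sets of cells 1 cell stood apart from the others of its group by Dixon's test at the 95% level, where chance alone gives about 1 in 20, or 13.2. MM cell 16 held 7 of these values, MM cell 19 held 6 and JG cells 5 and 6 held 5 each. Many of the genes were looked at because a single cell held them, so the excess over chance measures nothing by itself.

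In JG cell 4 Tra2a (13.25), Chpt1 (12.66) and Junb (12.29) lay above and Chchd10 (8.32) below the other cells. In JG cell 5 H1f10 (12.66), Cldn5 (10.77), Gpx3 (12.37), Miox (12.63) and Uqcrfs1 (8.33) lay above. In JG cell 6 Prdx2 (11.17), Mfap2 (9.28), Pcna (11.64) and H4c8 (12.73) lay above and Igfbp7 (10.53) below. In JG cell 7 Snai1 (11.00), Nnat (6.86) and Myl9 (12.79) lay above and 6330403K07Rik (6.64) below. In JG cell 8 Pln (12.32), Des (10.60) and Ier2 (10.93) lay above.

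In MM cell 14 Birc5 (11.16), Emcn (11.77) and Fbln1 (11.18) lay above the other cells. In MM cell 15 Rida (12.06), Meis1 (11.00) and Usp9y (4.79) lay above. In MM cell 16 Uty (6.29) and the median of the histone list (7.45) lay above, while 2610318N02Rik (5.86), Tead2 (7.54), Mfap2 (8.22), Ndufb8 (7.20) and Pcna (7.44) lay below. Cell 16 also had the lowest share of named probe sets above background among MM cells (12.2%). In MM cell 19 H2bc4 (10.98), Hspb1 (10.61), Lgmn (10.98), Col3a1 (10.62), Postn (9.34) and Igf2bp1 (9.95) lay above.

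The first pattern is the set of genes higher in JG cells than in diluted cortex. For Mgp, Crip1, Ptp4a3, Fxyd1 and Gm13889, MM cells exceeded diluted cortex by at most 0.85, below the receptor 99th percentile of 1.45. No single MM cell exceeded it by more than 1.20, so the rise of these genes was not seen in MM cells, amplified alike. These genes too were picked by this value, so it cannot serve as a test of a by-product of amplifying 1 cell. Over all 10 genes of the rule, 4 (n-R5s136, Gm13213, H1f10 and Tns1) exceeded the receptor 99th percentile. A by-product behind the whole pattern would need all 10. For these 4 genes, and for Tra2a at 1.45, on the limit itself, a by-product and a difference of cell type cannot be told apart, because the genes were sorted by the value that would test it. For the first 5 genes a by-product and a difference of cell type both stay open and were not tested apart.

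The second pattern is the low level of lysosomal, respiratory and proximal tubule genes in JG cells. Among random lists with the same level in diluted cortex, the lysosome list lay at percentile 17.3 and the respiratory chain list at 52.8, so loss of transcripts when 1 cell is amplified may account for both. In MM cells, amplified alike, these lists lay at percentiles 0.300 and 88.2. By group means, 18 of 19 respiratory chain genes stood above background in MM cells and 12 in JG cells. The matched random lists fell less in MM cells, with medians of -2.44 and -2.68, against -3.65 and -3.97 in JG cells. The shortfall at a given cortex level thus differed between the groups. The lysosome medians themselves were alike, at -4.28 in MM and -4.08 in JG cells. In JG cells the proximal tubule list lay at percentile 0.04, below the central range of random lists with the same level in diluted cortex. Genes of those random lists can differ by cell type too, so the lists do not show what loss alone gives. A difference of cell type stays open for all 3 lists and was not tested apart from loss.

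The third pattern is the difference between the 2 cortex groups, in which dilution, amplification and kit are confounded. Across probe sets, log2 fold change fell with the span of the gene (Spearman -0.374), although not in the shortest genes, with medians of 0.26 at 2.06 kb, 0.52 at 4.72 kb, 0.59 at 8.20 kb and -0.62 at 187 kb, so a shortfall of long genes in diluted cortex may account for part of it. Of the median size of the 20 named changes 91.7% was left once this trend was taken off. The medians of the trend ran only between 0.59 and -0.62, and these genes held the largest changes, so most of their size had to remain. The share left therefore decides nothing about span as their cause. Loss of RNA without a poly(A) tail and other causes cannot be told apart, because the small nucleolar RNA median of -0.58 missed the threshold and that of the histones was 0.43. The noncoding RNAs Rn7sk (-8.21) and Malat1 (-7.47), with the largest falls among the named genes, belong to neither list and were not part of this test. Among the 10 splits of the 6 libraries, only 1, the real one, gave 14599 limma calls and the highest other gave 0, but 10 splits are too few for a share under 0.05.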

How the results depend on the processing

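Centring on the receptors, leaving out JG cells 4 and 5 together, and all alternatives for MM cells against diluted cortex were chosen after the data were seen. Signal over background limits all cell comparisons, since only 7.51% to 23.0% of named probe sets per cell exceeded the receptor 99th percentile. Of the named genes, 267 values kept their direction and moved by less than the spread between cells and 53 moved by more for JG cells against diluted cortex, 296 and 4 for MM against JG cells, and 238 and 22 for MM cells against diluted cortex. Over the list medians of these comparisons 43, 48 and 23 values changed sign, 21, 5 and 19 of them where the median exceeded the spread between samples. The cause was not tested for any change below unless stated.

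JG cells against diluted cortex. With median centring the proximal tubule median was -5.36 and the renin cell median 0.18, and signs turned for immediate early genes (-0.17), stroma (-0.25), podocyte (-0.0807), smooth muscle (-0.15), erythroid (-0.34), ureteric bud (-0.43), cell cycle (-0.43) and Y-linked genes (-0.33). With quantile normalization small nucleolar RNA (-0.00911), ureteric bud (-0.22), cell cycle (-0.11) and Y-linked genes (-0.50) turned, and proximal tubule was -4.51 and smooth muscle 0.58. Centring on the receptors takes off their shift by construction and turned the cAMP pathway (-0.43), cap mesenchyme (-0.28), immediate early genes (-0.71), fibroblast (-0.35), stroma (-0.80), nascent nephron (-0.50), pericyte (-0.22), podocyte (-0.62), renin cell (-0.36), histones (-0.25), small nucleolar RNA (-0.37), smooth muscle (-0.69), erythroid (-0.88), ureteric bud (-0.97), cell cycle (-0.97) and Y-linked genes (-0.87), with proximal tubule at -5.90. Against standard-labelled cortex the cAMP pathway (-0.75), collecting duct (0.0486), endothelium (0.14), macrophage (0.42) and Y-linked genes (-2.31) turned, and proximal tubule was -4.67. Group medians gave proximal tubule -5.18 and renin cell 0.45 and turned ureteric bud (-0.0718), cell cycle (-0.0498) and ribosomal proteins (0.11). Dim members left out turned cell cycle (-0.20) and Y-linked genes (-3.31, Eif2s3y alone), and means of linear values gave smooth muscle 1.08. Without JG cells 4 and 5 proximal tubule was -5.16 and smooth muscle 0.72, and ureteric bud (-0.12) and ribosomal proteins (0.17) turned. Leaving out 1 sample in turn gave -5.15 to -4.79 for proximal tubule, 0.46 to 0.82 for renin cell and 0.30 to 0.47 for smooth muscle, and turned ureteric bud without JG cell 5 (-0.0244) and cell cycle without JG cell 8 (-0.0956) or diluted library A (-0.0744).

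MM against JG cells. With median centring small nucleolar RNA (0.00444), the cAMP pathway (0.0201), lysosome (0.11), thick ascending limb (0.0656), intercalated cell (0.00514), fibroblast (0.0517), cap mesenchyme (0.0699) and Y-linked genes (0.11) turned, with quantile normalization lysosome (0.0722) and Y-linked genes (0.13), and with dim members left out lysosome (0.27). Centring on the receptors turned endothelium (0.0221), pericyte (0.00841), podocyte (0.0106), small nucleolar RNA (0.0734), cap mesenchyme (0.14), the cAMP pathway (0.09), intercalated cell (0.07) and fibroblast (0.12), and also smooth muscle (0.0287), lysosome (0.18), thick ascending limb (0.13), collecting duct (0.021) and Y-linked genes (0.18). Group medians turned ribosomal proteins (-0.0298), stroma (-0.0551) and histones (-0.0395), and means of linear values stroma (-0.0235). Means of linear values gave a cell cycle median of 1.42. Leaving out 1 cell in turn gave 0.15 to 1.09 for cell cycle, 0.11 to 0.57 for fetal growth and -0.16 to -0.03 for cap mesenchyme, and turned lysosome (up to 0.23), thick ascending limb, stroma, histones and Y-linked genes.

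MM cells against diluted cortex. With median centring fibroblast (-0.00518), nascent nephron (-0.062), podocyte (-0.10), ribosomal proteins (-0.10) and smooth muscle (-0.0565) turned, with cap mesenchyme at 0.43 and proximal tubule at -5.59. Y-linked genes turned too (-0.22), as under quantile normalization (-0.37), centring on the receptors (-0.69) and with dim members left out (-2.70, Eif2s3y alone). With quantile normalization immediate early genes (0.10) and fibroblast (-0.0897) turned, with cap mesenchyme at 0.35 and proximal tubule at -4.96. Centring on the receptors turned the Notch (-0.035) and cAMP (-0.43) pathways, cap mesenchyme (-0.0439), fibroblast (-0.48), stroma (-0.11), nascent nephron (-0.54), pericyte (-0.18), podocyte (-0.57), histones (-0.0679), ribosomal proteins (-0.57), small nucleolar RNA (-0.22) and smooth muscle (-0.53), with proximal tubule at -6.07. Leaving out 1 sample in turn gave 0.66 to 0.82 for cap mesenchyme and -5.34 to -5.16 for proximal tubule.

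Diluted against standard-labelled cortex. The 20 named genes kept direction and threshold in all 260 repeats with limma. Median centring gave 8932 higher and 5846 lower, and a filter at the 75th percentile, which tests fewer probe sets, left 4467 lower. Leaving out 1 library in turn gave 6813 to 7330 higher, 6618 to 7060 lower and 13431 to 14342 in all. Pairing by letter stayed open. Deviations correlated at 0.156 (A), 0.150 (B) and 0.0349 (C), against -0.177 to 0.0547 (diluted C with B) across letters. As a replicate block the letters gave 7461 higher and 7170 lower, 14631 in all, and collecting duct and cAMP at limma camera adjusted p = 0.0557 each.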

Other observations

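The rule for named genes was also applied to MM cells against diluted cortex, a choice made after the data were seen, as were all other values in this part.

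Mest, an imprinted gene of fetal growth, measured 10.67 ± 2.76 (SD over 4 cells) against 5.97 in diluted cortex, a difference of 4.70. Tead2, a transcription factor of the Hippo pathway, was higher by 4.24, Snai1, a repressor of epithelial genes, by 4.19, and Crabp2, a retinoic acid binding protein, by 3.78. The microfibril protein Mfap2 was higher by 3.69, the proteolipid Nnat, an imprinted gene, by 3.73, the kinetochore protein Cenph by 4.03 and the replication factor Pclaf by 3.96. The remaining genes of the rule were 2610318N02Rik (5.24) and 6330403K07Rik (4.04), and receptors were 0.81 higher. Several of these means join high and low MM cells. Cenph ran from 4.48 to 11.5 over the 4 cells, Crabp2 from 6.26 to 12.10, Nnat from 6.75 to 11.56 and 2610318N02Rik from 5.86 to 12.12. Pclaf was steadier, at 10.03 to 11.91. The other probe set of 2610318N02Rik differed by 1.59 and that of Pclaf by 2.23. Except for Snai1, Pclaf and Mfap2, the diluted cortex means of these genes lay below the receptor 99th percentile of its arrays, so the differences are bounds.

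The genes lowest in MM cells included Gatm, Slc27a2 and Fbp1 of the proximal tubule list, with Gatm at -7.26, Slc27a2 at -7.16, Cltrn at -7.06, Ugt2b38 at -6.96, Fbp1 at -6.89, Tmem174 at -6.78, the arachidonic acid epoxygenase Cyp2j5 at -6.74 and Spink1 at -6.72. The phospholipid enzyme Chpt1 differed by -7.12 and Plscr2 by -6.91. The MM means of these 10 genes lay below the receptor 99th percentile of every MM array, so these differences are bounds too. Among random lists with the same level in diluted cortex, medians in MM cells lay at percentile 0 for proximal tubule, 0.300 for lysosome, 1.42 for thick ascending limb, 0.780 for renin cell, 88.2 for respiratory chain and 100 for ribosomal protein genes. In JG cells the thick ascending limb list lay at 1.54, the renin cell list at 58.5 and the ribosomal protein list at 100.

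Across 1755 genes above 10 in diluted cortex, the difference from diluted cortex correlated with gene span at -0.345 (Spearman) in JG cells and -0.343 in MM cells. Genes are not independent replicates, and no test was made.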
